A study of Mus musculus with 2 samples.

How the data were processed

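Total RNA of mouse neural stem cells grown in suspension was sequenced in 1 library labelled wild type and 1 library labelled Hikeshi conditional knockout (cKO). The groups were taken from the genotype labels, and each column of the deposited table was matched to its library by the genotype in the column name. Libraries were made with standard Illumina methods after column extraction of total RNA, per the labels' protocols. The genome build was GRCm38.p6, per the submitters' processing notes. The aligner, the counting tool, the gene annotation, the strand setting and the part of the gene removed by the deletion are not given in the sources used here.

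The authors deposited 1 table with 4 kinds of value for each library. The first is an estimated count of reads per gene, named a read count per the file headers. Of these values 89.8% in the cKO-labelled library and 90.0% in the wild-type-labelled library were whole numbers, and the rest had up to 2 decimals. The authors also deposited TPM, named so per the file headers, which summed to 1000000 in the cKO-labelled and 999999 in the wild-type-labelled library. The deposited FPKM values were likewise named per the file headers. The fourth kind is a signal that the file headers call a normalized read count. In the deposited table this signal equalled the read count rounded up to a whole number times 1 constant per library, 1.00261 in the cKO-labelled and 0.997397 in the wild-type-labelled library, within a tolerance of 1e-06. How the authors obtained those constants is not given in the sources used here.

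The table listed 15953 genes by symbol and Entrez number, and no gene was at 0 in both libraries. Of these, 15909 were matched by gene number to a RefSeq gene table of GRCm38.p6, which supplied the coordinates. Among the matched genes 15827 were protein-coding and 57 long noncoding, so the absence of a noncoding gene from the table says nothing about its level. None of the 13 mitochondrially encoded protein genes was listed, so their levels cannot be given. Transcript GC content and length came from GENCODE transcripts and were available for 97.9% of the genes kept.

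The estimated counts were rounded to whole reads, summed to 18912683 reads in the cKO-labelled and 18839079 reads in the wild-type-labelled library, and divided by those totals to give CPM (reads per 1000000 reads counted). A gene was kept when it reached 1 CPM in at least 1 library. The difference of a gene is log2 of the ratio of CPM values, cKO over wild type, after adding 1 CPM to each, which understates the difference of low genes. Genes at least 2-fold apart on that scale were counted. Folds in the text are ratios of CPM without the added value.

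With 1 library per group there were no replicates, so no test between genotypes was possible and no p-value is given. Each fold carries a 95% interval from the exact conditional binomial (Clopper-Pearson) distribution of the reads in the 2 libraries. Such an interval compares these libraries, not the genotypes, and covers counting error at most. Reads without molecular identifiers are not independent molecules, so the interval can be too narrow even for counting error. A gene with 0 reads in a library was set against a floor of 3 reads in that library, 0.159 CPM, and its fold is given as at least that size. The floor is a convention, and the lower limit of the counting interval of such a gene is smaller.

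The comparison, the filter, the thresholds, the rule for named genes and 39 gene lists were fixed before the data were examined. The lists covered neural stem and radial glia markers, neurogenic factors, neuronal, astrocyte and oligodendrocyte lineage markers, cell cycle phases and inhibitors, p53 targets, the HSP70 family and other chaperones, stress responses, apoptosis, hypoxia and glycolysis, mitochondria, cholesterol synthesis, ribosomal proteins, signalling pathways, immediate early and interferon genes, nuclear transport, genes near Hikeshi, extracellular matrix, other cell types, brain regions, sex-linked genes and histones. Lists can share genes, such as Hspa4l, Dll3, Mfng, Hes5 and Notch3, and a shared gene counts in each, so the lists are not independent. For each list the kept members at least 1.5-fold higher or lower were counted. Its median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Lists with under 3 kept members are given as single values.

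Named genes were Hikeshi, the 12 genes with the largest difference in each direction among those with at least 5 CPM and 50 reads in the higher library, up to 2 members per direction and list at least 1.5-fold apart, and a fixed set of anchor genes. Predicted or unnamed models, pseudogenes and further copies of near-identical genes were left out of the 12. A few genes that the rule takes are not reported here. Genes outside the rule were chosen after their values were seen, which holds for Cers1, Entpd4b, H3c15, Cspg4, Lhfpl3 and the plotted Hsph1 in the results and for those said to be so in the closing section.

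The computation was run on simulated Poisson counts, with the mean of each gene taken from these libraries pooled. Such counts hold no variation between cultures or library preparations. They do not tell how many genes would differ between cultures of the same genotype. Sampling noise alone put 0 of 12313 unchanged genes 2-fold apart and 21 of them 1.5-fold apart. Of genes changed 1.5-fold, 0 of 70 passed the 2-fold threshold. Of genes changed 2.5-fold, 60 of 66 passed it, and of genes changed 4-fold, 62 of 63 did. The intervals held the true ratio for 1901 of 2000 simulated pairs of Poisson counts. Those pairs had fixed means not taken from these libraries, so this checks the computation of the interval only.

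Alternatives covered other scalings (TMM from edgeR, median centring, leaving out the 50 highest genes), pseudocounts of 0.1 and 5, no filter or a filter of 5 CPM, thresholds of 1.5-fold and 4-fold, named symbols only, unmatched random lists and the mean in place of the median. Removal of the GC trend, the deposited TPM, the deposited normalized read counts and counts without Y-linked genes were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, were used.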

Results

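The data were gene-level read counts from mouse neural stem cells grown in suspension, the self-renewing progenitors that give rise to neurons, astrocytes and oligodendrocytes. There was 1 library from cells labelled wild type and 1 from cells labelled Hikeshi cKO. Hikeshi is a carrier that brings HSP70 chaperones into the nucleus, and the series title names proliferation and differentiation as its subject. The libraries were of nearly equal depth, with 18912683 reads (cKO) and 18839079 reads (wild type) and with 15239 and 15326 genes detected. The 10 most abundant genes took 5.13% and 5.08% of the reads.

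The targeted gene was read first. Hikeshi (Entrez 67669, chromosome 7, 89918685 to 89941223, GRCm38.p6) had 640 reads in the library labelled cKO and 718 in the library labelled wild type, or 33.8 against 38.1 CPM. The ratio was 0.888 (95% counting interval 0.797 to 0.989), so the level was only slightly lower in the library labelled cKO. Deposited TPM values of Hikeshi were 82.35 and 85.18. A conditional deletion can leave the remaining exons transcribed, and counts over the whole gene then check nothing. The level of Hikeshi therefore does not settle the genotype, which is taken from the labels. Every direction below is drawn between the library labelled cKO and the library labelled wild type. The implied length of Hikeshi and the reads of Prm1 are weighed in the closing section and settle nothing either.

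The libraries also differed in 4 sex-linked genes of the Y chromosome, whose reads lay almost only in the library labelled cKO. Eif2s3y, a translation initiation factor subunit, had 1265 reads against 0 (at least 420-fold higher against the floor, lower counting limit 341). The RNA helicase gene Ddx3y had 846 against 0 (at least 281-fold, limit 228) and the histone demethylase gene Kdm5d 515 against 0 (at least 171-fold, limit 139). Uty had 305 reads against 1, a ratio of 304 (interval 54.1 to 12039). A difference between the libraries thus coincided with a difference in Y-linked expression as well as with the genotype labels, and this holds for each gene group below.

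Of 12618 genes kept, 158 were at least 2-fold higher and 486 at least 2-fold lower in the library labelled cKO, while 85.6% lay within 1.5-fold. The median difference of all kept genes was -0.02 on the log2 scale. In the direction of lower expression, oligodendrocyte lineage, astrocyte and hypoxia genes stood out. In the direction of higher expression, heat shock and cell cycle genes did.

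**Figure D1:**
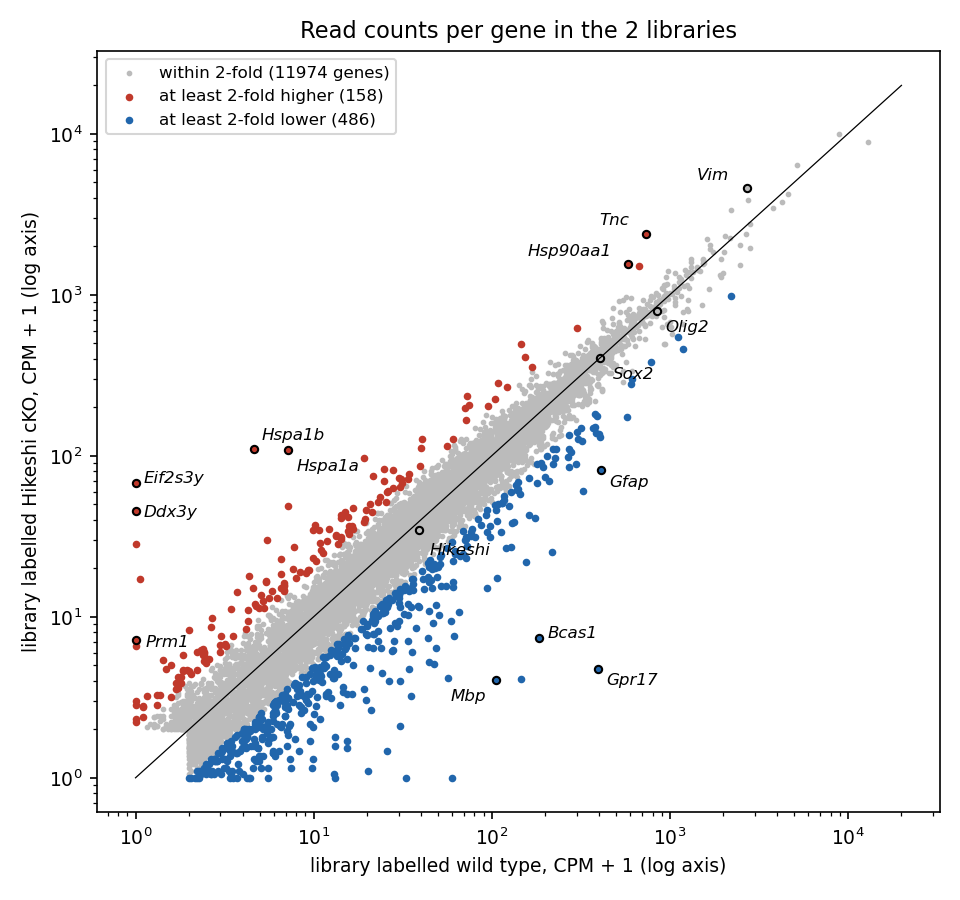
Each point is 1 of 12618 kept genes, with CPM + 1 in the library labelled wild type on the x axis and in the library labelled Hikeshi cKO on the y axis, both on log axes, and the line marks equal values. Red points are the 158 genes at least 2-fold higher and blue points the 486 at least 2-fold lower in the library labelled cKO, and Hikeshi lies near the line.

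Genes of the oligodendrocyte lineage, which makes myelin, were lower in the library labelled cKO. Of 19 kept members of the list, 15 were at least 1.5-fold lower and 0 higher, with a median of -2.26, below all 10000 matched random lists. Gpr17, a receptor of differentiating oligodendrocyte precursors, had 71 reads against 7423 and was 105-fold lower (interval 83.1 to 135). The myelin gene Mbp was 34.2-fold lower (26.3 to 45.2), and Bcas1, a marker of early myelinating cells, 28.8-fold (24.0 to 34.8). Sox10, a transcription factor of the lineage, was 17.5-fold lower (13.5 to 23.1), and Pdgfra, the growth factor receptor of the precursors, 7.42-fold (6.68 to 8.26). Enpp6, with 2 reads against 364, and the myelin glycoprotein gene Mag, with 1 against 225, were 183-fold (50.2 to 1514) and 226-fold (40.1 to 8961) lower. The transcription factor genes Olig1 and Olig2, also made by progenitors in culture, differed by little, at 1401 against 1468 and 787 against 848 CPM. Cspg4 and Lhfpl3, markers of the precursors named after their values were seen, were the other members within 1.5-fold (log2 differences of -0.25 and -0.48).

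Outside that list, Gal3st1, an enzyme of the myelin lipid sulfatide, was 27.2-fold lower in the library labelled cKO (14.6 to 57.4), Phactr3 26.6-fold (17.2 to 43.3) and Tmem100 15.3-fold (11.2 to 21.5). Lims2 was 52.1-fold lower (27.2 to 115) but spans Gpr17 on chromosome 18, and without a known strand setting their reads may not be separable. The reads of both genes together were 99.0-fold lower (79.5 to 125). Gdf1 had 0 reads against 600 (at least 201-fold lower against the floor, lower counting limit 163) and shares its locus with Cers1, which had 543 against 349. Summed, Gdf1 and Cers1 had a ratio of 0.570 (0.512 to 0.634), so the value of Gdf1 alone is uncertain.

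Astrocyte markers were lower as well, with 16 of 20 kept members at least 1.5-fold lower and 0 higher in the library labelled cKO, and a median of -1.15, again below all random lists. Gfap, the astrocyte intermediate filament, was 5.13-fold lower (4.86 to 5.43), S100b 5.42-fold (3.85 to 7.80) and the water channel gene Aqp4 4.85-fold (4.40 to 5.35).

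**Figure D2:**
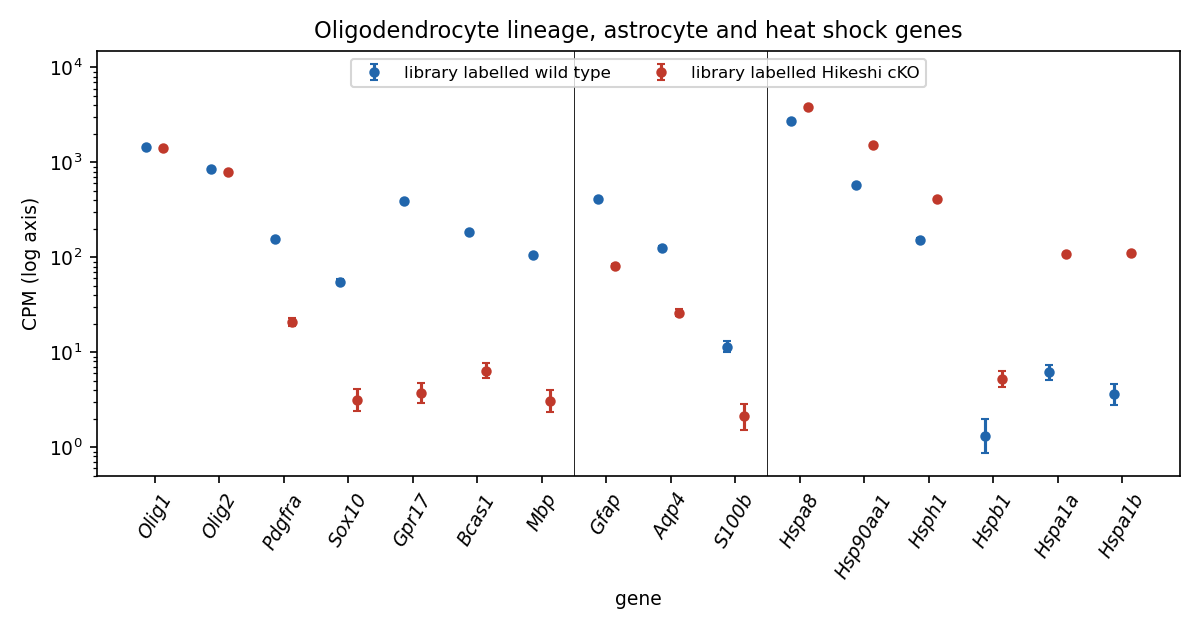
CPM of 16 oligodendrocyte lineage, astrocyte and heat shock genes is shown on a log axis. Blue marks the library labelled wild type and red the library labelled Hikeshi cKO. Bars are exact 95% Poisson intervals of the reads, which cover counting error at most. Olig1 and Olig2 nearly coincide, Gpr17 lies at 394 against 3.75 CPM, and Hspa1b at 3.61 against 110 CPM.

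The other stages of the lineage differed less. Of 22 stem and radial glia markers, 3 were at least 1.5-fold higher and 5 lower, with a median of -0.12 at percentile 3.09 of the random lists. The progenitor transcription factor genes Sox2 (ratio 0.993, 0.962 to 1.02) and Pax6 (0.883, 0.767 to 1.02) did not differ detectably. Nestin (Nes), the progenitor intermediate filament, was 1.37-fold higher (1.34 to 1.41) in the library labelled cKO, vimentin (Vim) 1.69-fold (1.67 to 1.70) and the matrix protein gene Tnc 3.29-fold (3.23 to 3.35). Hes5, a target of NOTCH, was 2.57-fold lower (2.25 to 2.93), Prom1 1.92-fold (1.52 to 2.45) and the lipid carrier gene Fabp7 1.51-fold (1.49 to 1.54).

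Of 13 neurogenic factors, 0 were at least 1.5-fold higher and 4 lower (median -0.16, percentile 19.9), among them Dll3 at 2.69-fold (2.43 to 2.99) and Mfng at 2.62-fold lower (1.77 to 3.96). Eomes, with 17 reads against 0, and Neurog2, with 2 in each library, were below the filter. Neuronal markers were split, with 4 of 22 higher and 6 lower in the library labelled cKO (median -0.23, percentile 1.60). The migrating neuroblast gene Dcx was 10.3-fold lower (8.21 to 13.2) and Ncam1 2.12-fold (2.04 to 2.21), while the neurofilament gene Nefm was 2.49-fold higher (2.10 to 2.97) and Reln 2.53-fold (2.17 to 2.95). Tubb3 and Map2 were 1.21-fold (1.04 to 1.40) and 1.17-fold (1.14 to 1.203) lower. The percentile of the neuronal list returned inside the central 95% of random lists without the filter on low genes and with the mean, so its place depends on that choice.

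**Figure D3:**
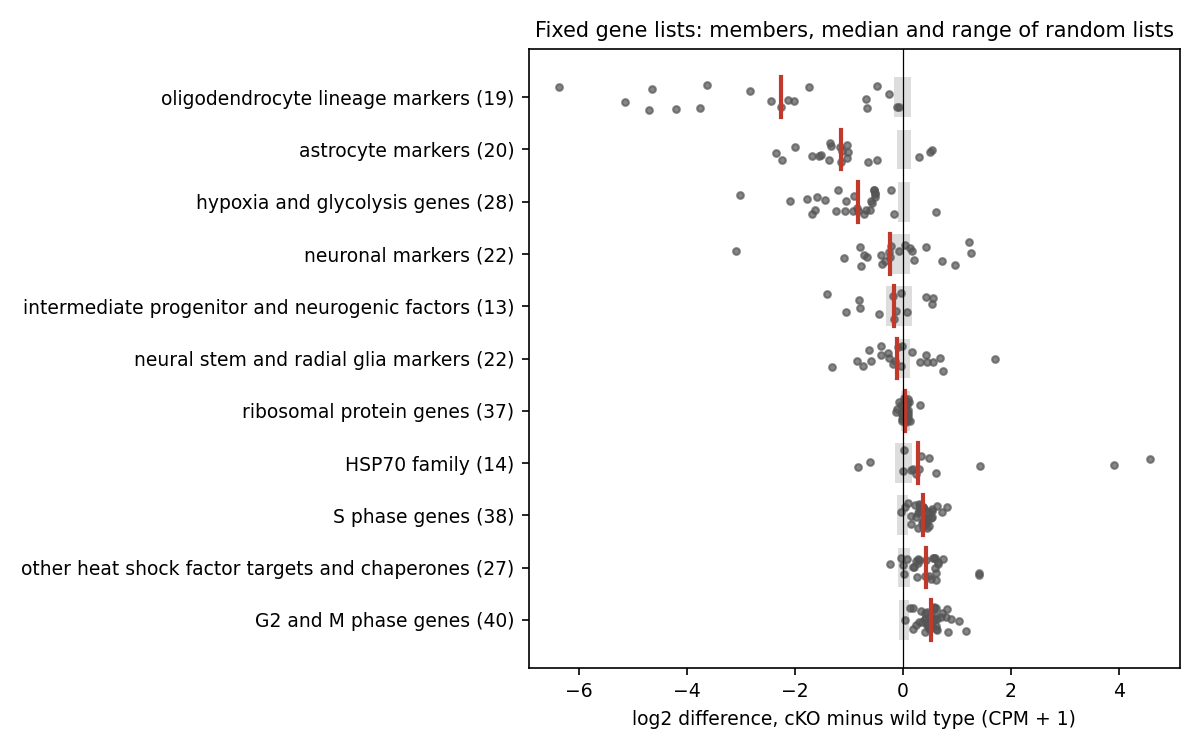
Log2 difference, cKO minus wild type as labelled (CPM + 1), of the kept members (grey points) of 11 fixed gene lists, with the number of members after each name, the list median (red line) and the central 95% of medians of 10000 matched random lists (grey band). The medians run from -2.26 for oligodendrocyte lineage markers to 0.51 for G2 and M phase genes, and that of ribosomal protein genes is 0.04.

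Proliferation genes were higher in the library labelled cKO, nearly all of them by less than 2-fold. All 40 genes of G2 and M phase lay above 0, 14 of them at least 1.5-fold higher (median 0.51), and 37 of 38 S phase genes lay above 0, 3 of them at least 1.5-fold higher (median 0.38). Both medians lay above all 10000 random lists. The kinesin genes Cenpe and Kif20b were 2.31-fold (2.06 to 2.60) and 2.14-fold (1.83 to 2.51) higher, the S phase cyclin gene Ccne2 1.81-fold (1.58 to 2.08) and the DNA polymerase gene Pola1 1.69-fold (1.5005 to 1.90). The proliferation marker Mki67 was 1.66-fold higher (1.58 to 1.74), Top2a 1.41-fold (1.36 to 1.47), Ccnb1 1.34-fold (1.27 to 1.40), Mcm5 1.25-fold (1.18 to 1.32) and Ccnd1 1.38-fold (1.36 to 1.40). Genes of low GC content were slightly higher in the same library, with a median of 0.13 in the tenth of lowest GC and -0.10 in the tenth of highest GC. With that trend removed the medians were 0.48 for G2 and M phase and 0.37 for S phase.

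Among 13 cell cycle inhibitors 1 was higher and 1 lower (median 0.10 but mean -0.06, percentile 84.4). Cdkn1c, which encodes p57, was 8.90-fold lower (7.24 to 11.0) in the library labelled cKO, and Cdkn1a, which encodes p21, 1.59-fold higher (1.55 to 1.64). Of 24 targets of p53, 4 were higher and 1 lower (median 0.24), and 1 of 10000 random lists reached that median. Plk2 was 2.15-fold higher (2.03 to 2.28) and Ddit4 2.03-fold lower (1.93 to 2.13). Apoptosis genes were near their random lists (2 of 23 higher, 1 lower, median 0.05, percentile 79.8). Among these Hrk was 1.70-fold (1.23 to 2.37) and Casp8 1.60-fold (1.27 to 2.02) higher, and Birc3, with 1 read against 25, was 25.1-fold lower (4.11 to 1030).

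Heat shock genes were higher in the library labelled cKO. The inducible HSP70 genes Hspa1b and Hspa1a had 2075 reads against 68 and 2027 against 116, ratios of 30.4 (23.9 to 39.3) and 17.4 (14.4 to 21.2). As near-identical neighbours they can share reads, and their sum was 22.2-fold higher (19.2 to 25.9). Of 14 kept HSP70 family members 4 were at least 1.5-fold higher and 2 lower (median 0.28, percentile 99.96), and the constitutive Hspa8 and the endoplasmic reticulum member Hspa5 were 1.41-fold (1.39 to 1.42) and 1.23-fold (1.2002 to 1.27) higher. Hspa12a was 2.17-fold lower (1.46 to 3.27) and Hspa2 1.56-fold (1.34 to 1.81). Of 27 other chaperones and heat shock factor targets 9 were higher and 0 lower, with a median of 0.44 above all random lists. Hspa4l belongs to both lists and is counted as higher in each. Hsp90aa1, the inducible HSP90, was 2.65-fold higher (2.59 to 2.71), the small heat shock gene Hspb1 3.94-fold (2.52 to 6.39), and the regulator Hsf1 1.14-fold (1.03 to 1.27).

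Other stress response lists had medians below 0 in the same comparison. Of 30 genes of the unfolded protein and integrated stress responses 1 was higher and 3 lower (median -0.08, percentile 4.64), with Atf3 1.71-fold higher (1.42 to 2.07), Chac1 1.93-fold (1.66 to 2.26) and Trib3 1.80-fold (1.46 to 2.23) lower. Of 22 oxidative stress genes 1 was higher and 1 lower (median -0.11, percentile 2.06), Txn1 being 1.76-fold higher (1.72 to 1.81) and Gsta4 2.18-fold lower (1.82 to 2.61). Interferon response genes lay within their random lists (0 of 20 higher, 1 lower, median -0.16, percentile 22.9), the 1 being Rtp4 at 2.14-fold lower (1.28 to 3.68). Of 32 nuclear transport factors, the class to which Hikeshi belongs, 0 were 1.5-fold apart, yet 27 lay above 0 and the median of 0.23 lay above all random lists.

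Hypoxia and glycolysis genes were lower in the library labelled cKO, with 19 of 28 at least 1.5-fold lower and 1 higher, and a median of -0.84 below all random lists. The lactate exporter gene Slc16a3 was 9.16-fold lower (7.61 to 11.1) and the hypoxia-induced mitophagy gene Bnip3 4.36-fold (4.03 to 4.72), while the phosphofructokinase gene Pfkp was 1.53-fold higher (1.45 to 1.61). Among 36 respiratory chain genes 0 were 1.5-fold apart (median 0.01 but mean -0.01, percentile 21.4), and the same held for 37 ribosomal protein genes (median 0.04, percentile 45.8). Of 24 cholesterol synthesis genes 0 were higher and 1 lower (median -0.04, percentile 6.24), which was Tm7sf2 at 1.88-fold lower (1.76 to 2.01). None of the 13 fixed mitochondrially encoded genes was listed.

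Of 22 NOTCH pathway genes 1 was higher and 7 lower (median -0.17, percentile 2.42). Among the lower members, Dll3, Mfng, Hes5 and Notch3 are also counted as lower in the neurogenic, stem or pericyte lists. The feedback inhibitor gene Nrarp was 2.81-fold lower (2.46 to 3.21) and the ligand gene Jag1 2.16-fold higher (1.91 to 2.44). This percentile lay next to the limit and passed out of the outer 5% under most alternatives. Of 17 WNT targets 4 were higher and 4 lower (median 0.06, percentile 88.5), with Nkd1 2.42-fold higher (2.16 to 2.72), Lef1 at 33 reads against 2 (ratio 16.4, 4.204 to 141), and Tcf7l2 2.52-fold (2.02 to 3.17) and Sfrp1 2.20-fold (1.51 to 3.25) lower. Of 12 SHH pathway genes 1 was higher and 0 lower (median -0.04 but mean 0.02, percentile 52.8), Shh itself at 2.85-fold (2.16 to 3.79). BMP and TGF-beta targets had 6 of 17 higher and 1 lower (median 0.11, percentile 96.0). Ccn2 was 10.3-fold (5.01 to 24.7) and Tgfbi 4.30-fold (2.47 to 7.93) higher. Bmp4 had 0 reads against 64 (at least 21.4-fold lower against the floor, lower counting limit 16.9). ERK pathway genes had 2 of 18 higher and 2 lower (median 0.09 but mean -0.01, percentile 86.6), with Fosl1 2.35-fold (1.91 to 2.90) and Epha2 1.86-fold (1.60 to 2.16) higher and Ier3 2.33-fold lower (2.11 to 2.58). Immediate early genes went both ways (4 of 20 higher, 5 lower, median -0.12, percentile 21.5), with Klf4 2.10-fold (1.65 to 2.67) and Klf6 1.74-fold (1.64 to 1.84) higher and Egr1 2.68-fold (2.51 to 2.86) and Egr3 2.39-fold (1.86 to 3.09) lower.

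Extracellular matrix genes also went both ways, with 6 of 25 higher and 7 lower (median 0.18, mean 0.02, percentile 99.7). Spp1 was 2.99-fold higher (2.62 to 3.43), fibronectin (Fn1) 4.15-fold lower (3.63 to 4.76) and Timp3 2.87-fold lower (2.57 to 3.21). Of 15 forebrain regional genes 1 was higher and 4 lower (median 0.16, mean -0.12, percentile 98.2). Emx2 was 1.90-fold higher (1.70 to 2.13), and Otx2 and Six3 had 3 reads each against 42 and 40, ratios of 14.1 (4.49 to 70.9) and 13.4 (4.26 to 67.6) in favour of the library labelled wild type. Of the midbrain, hindbrain and spinal cord genes only En2 (0.33) and Gbx2 (0.54) were kept, given as log2 differences.

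Markers of other cell types were sparse. Few microglia markers were kept, among them Cd68 with a log2 difference of 0.55, and no red blood cell gene was kept. The 3 endothelial markers kept were within 1.5-fold (median -0.06, percentile 65.3). Of 9 pericyte and fibroblast markers 1 was higher and 4 lower (median -0.58, percentile 0.82), with Prrx1 2.37-fold higher (2.13 to 2.65), and Notch3 2.27-fold (1.93 to 2.67) and Myl9 2.19-fold (1.69 to 2.85) lower. Ependymal and choroid plexus markers had 0 of 6 higher and 3 lower (median -0.61, percentile 7.69), with Aqp1 at 6 reads against 27. Neural crest and Schwann cell markers had 2 of 7 higher and 2 lower (median -0.45, percentile 1.35). Both lower members, Sox10 among them, are also held by the oligodendrocyte list, while Mitf and Ets1 were 1.98-fold (1.48 to 2.66) and 1.62-fold (1.503 to 1.75) higher. The percentiles of the extracellular matrix, forebrain, pericyte, neural crest and oxidative stress lists came inside the central 95% of random lists under some alternatives.

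Genes near Hikeshi on chromosome 7 had 2 of 11 higher and 1 lower (median 0.04, percentile 65.8), which were Sytl2 at 2.30-fold (1.98 to 2.68) and Prss23 at 2.22-fold (2.01 to 2.46) higher and Ctsc at 1.64-fold lower (1.46 to 1.84). Of 6 replication-dependent histone genes 1 was higher and 0 lower (median 0.25, percentile 97.3). That gene, H3c14, had 35 reads against 0, but its near-identical copy H3c15 had 0 against 45, and their sum did not differ detectably (ratio 0.775, 0.483 to 1.23). Setting members with 0 reads to the floor left the medians of the oligodendrocyte, BMP and histone lists at -2.26, 0.11 and 0.25 and moved that of the sex-linked list from 5.17 to 4.95.

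Among the remaining genes with the largest differences, Prm1, a sperm chromatin protein gene (chromosome 16, 10796332 to 10796823), had 116 reads in the library labelled cKO and 0 in the other. It was at least 38.5-fold higher against the floor (lower counting limit 30.8). Syt4, a vesicle protein gene, was 7.78-fold higher (6.41 to 9.52), the potassium channel gene Kcna4 7.18-fold (4.43 to 12.3), Tm4sf1 6.51-fold (5.17 to 8.29), the retinoic acid synthesis gene Aldh1a3 5.25-fold (4.68 to 5.91) and Ecel1 4.90-fold (3.62 to 6.76). Entpd4 had 106 reads against 0, but its copy Entpd4b had 1186 against 1532, and their sum had a ratio of 0.840 (0.780 to 0.905), so the value of Entpd4 alone is uncertain.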

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

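The GC, TPM, normalized read count and Y-linked alternatives were chosen after the results were seen, and the rest were planned. With 1 library per group no library could be left out. No paired analysis was possible because each group had 1 library. A count is said to hold within 1.5 times its reported value, the share of higher genes within 10 percentage points, a gene within its 95% counting interval, and a list median within the 95% binomial interval of the median over its members. Of the counts of genes, their split and the Hikeshi level, 42 alternative values held and 8 moved. The count of genes 2-fold lower was 769 with a pseudocount of 0.1. With a pseudocount of 5 the counts were 73 higher and 193 lower, against 158 and 486. At 1.5-fold they were 532 and 1290, and at 4-fold 13 and 79, where the share of higher genes was 14.1% in place of 24.5%; these thresholds change the counts by construction. Hikeshi stayed between -0.28 (GC trend removed) and -0.05 (TPM). No scaling moved the median of all genes by over 0.1.

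Of the list medians 376 values held, 5 moved and 1, of a list outside the central 95%, reversed: the forebrain value was -0.12 with the mean. Counting all lists, 14 values of 9 lists switched sign, most of them near 0. Of the percentiles 376 kept their side of the central 95%, 28 came inside it and 13 passed out of it. The neuronal percentile was 8.265 without a filter on low genes and 22.3 with the mean, and the stem and radial glia percentile 1.14 with TPM. The cause was not tested. Oligodendrocyte, astrocyte, hypoxia, S phase, G2 and M phase, HSP70 and chaperone lists kept their side under every alternative run. The GC check of the histone list is void, because only 16.7% of its members had a GC value. Among named genes 736 values held and 271 moved. That check set differences with 1 CPM added against intervals of folds without it. A low gene can thus fall outside before any setting changes, and the intervals of highly counted genes are narrow. All 127 values held with a pseudocount of 0.1, while 33 moved with TMM, whose factors were only 0.992 and 1.008. The number of moved values is therefore no measure of dependence on processing. No named gene at least 1.5-fold apart changed sign, while Sox2 did with TMM (0.01) and the normalized read counts (0.0026), and Olig1 with the GC trend removed (0.01). Genes with few reads are limited by depth, as their intervals show.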

Other observations

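All of the tests in this part were chosen after the results were seen, as were the genes named in the next paragraph. Libraries are named by their labels, because the level of Hikeshi did not settle the genotype.

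Outside the fixed lists, several well-counted genes were lower in the library labelled cKO. Vxn had 24.2 CPM against 218, the matrix protein gene Tnr 59.1 against 324, the glutamate transporter gene Slc1a1 16.4 against 106, and Luzp2 4.07 against 46.2. In the opposite direction, the galectin gene Lgals1 was higher at 493 against 145 CPM, as were the collagen gene Col18a1 at 233 against 71.4, Angpt2 at 126 against 39.9 and the neuropeptide precursor gene Vgf at 207 against 73.2. Within the hypoxia list the same library was lower in the glucose transporter gene Slc2a1 (68.8 against 210 CPM) and in Vegfa (130 against 405). The interferon-inducible genes Ifi203 and Ifi202b had 31 reads against 375 and 3 against 122, or 12.1-fold (8.41 to 18.1) and 40.8-fold (13.6 to 201) lower, while Ifi204 of the same cluster on chromosome 1 had 11 against 17 and did not differ detectably (ratio 0.645, 0.273 to 1.46). Of the 4 X-linked partners of the Y-linked genes 3 were lower, Kdm5c 1.44-fold (1.37 to 1.51), Eif2s3x 1.37-fold (1.32 to 1.41) and Kdm6a 1.15-fold (1.03 to 1.30), and Ddx3x was 1.18-fold higher (1.15 to 1.22).

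The lower oligodendrocyte lineage genes are not explained by the GC trend, since the list median was -2.19 after its removal. A smaller share of committed oligodendrocyte lineage cells in the culture labelled cKO may account for them. The precursor gene Pdgfra was 7.42-fold and Gpr17 105-fold lower, but both belong to the list to be explained and are no separate evidence. The precursor markers Cspg4 (-0.25) and Lhfpl3 (-0.48, log2) differed far less, and a smaller share cannot be told apart here from lower expression per cell. A difference in sex stays open as well, with 1265 reads of Eif2s3y in that library and 0 in the other, because it coincides with the genotype labels. An effect of the Hikeshi genotype stays open too and is untested, with 1 library per group. For the same reason any other difference between the cultures stays open, here and for the heat shock genes below. The hypoxia and glycolysis list was lower in the same library too, with 19 of 28 members lower and 1 higher (median -0.84).

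The higher values of Hspa1a and Hspa1b are not an effect of reads shared between these copies, since each was higher and their sum was 22.2-fold higher. The higher chaperone list is not an effect of the GC trend, after whose removal it kept a median of 0.45. A handling response at harvest could raise the heat shock genes and stays open. The immediate early genes had a median of -0.12 with members going both ways, which decides nothing. The Hikeshi genotype is the biological difference the design names, and it remains an untested explanation. The difference in Y-linked reads coincides with the genotype labels here as well. The lower oligodendrocyte and astrocyte lists also leave open a different mix of cells, and neither was tested for the heat shock genes.

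Hikeshi was not lower by much in the library labelled cKO. A ratio of 1.13 in favour of the library labelled wild type goes against a deletion that removes most Hikeshi reads, with the labels as given or swapped, so it does not tell these apart, and a swap with a deletion that leaves the reads in place stays open. Deletion in a minority of the cells (ratio 0.888) could leave such a level. A shortened transcript still counted could as well: the length implied by reads and FPKM was 669 bases against 723, a shift at percentile 0.805 of 9194 genes, though such a shift can have other sources and the deleted part is not given in the sources used here. Germ cell RNA as the source of Prm1, at 116 reads against 0, found no sign among other spermatid genes but could not be excluded. Of 48 other spermatid genes looked for, 17 were listed, none with more than 6 reads in the library labelled cKO. Their summed reads were few in either library, 26 there against 68 (ratio 0.381, 0.233 to 0.607). Prm2, Tnp1 and Tnp2 were among those not listed, so their levels cannot be given. With so few reads, the listed genes cannot decide the question. A transgene that carries a protamine sequence, as some Cre constructs do, may be a source and is untested here.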
